A study of Mus musculus with 30 samples.

How the data were processed

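Genomic DNA from 26 mammary tumours and 4 normal mammary samples of female FVB mice was compared with normal spleen DNA by array comparative genomic hybridisation on 30 Agilent arrays. Sample DNA carried Cy5 (red) and spleen DNA carried Cy3 (green) on every array, with no dye swap. A log2 ratio above 0 therefore stands for more DNA in the sample than in the spleen reference.

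Per the file headers, the authors' scanner files were made by Agilent Feature Extraction 10.5.1.1 on 20 arrays and 10.7.3.1 on 10 arrays, with probe positions on the mouse build NCBI36 (mm8). The deposited processed signals are in units of intensity, after background subtraction, removal of a spatial trend and a linear dye factor per channel. The deposited log ratio of each spot is the log10 of red over green processed signal. The deposited value table holds log2 ratios in runs of equal value along the chromosomes, with 37 to 136 runs per array. Its values are therefore segmented, and neither the tool nor the centring behind them is given in the sources used here. Of its 30 columns, 27 correlated best with the array of the same sample, and the 3 that did not were normals. Of the mapped probes, 2 were absent from it, both on chromosome 6.

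The analysis started from the processed signals of the scanner files. Each array held 43020 spots that were not controls, and 42235 probes had a chromosome position, 40666 on the 19 autosomes and 1569 on chromosome X. Across all arrays, 131 values that the software marked as outliers were set to missing. The log2 ratio of red over green was averaged over spots of the same probe and centred on the median of the autosomal probes of its array. The median processed signal was 1005 to 1201 in green and 992 to 1196 in red. Between 35248 and 42853 spots per array were well above background in green and between 38175 and 42937 in red, with Trp53 tumour 4 lowest in both channels. The noise of an array, taken from differences between neighbouring probes, had an SD of 0.12 to 0.31 on the log2 scale. The number of arrays limits the precision.

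Segments of equal copy number were found by a penalised least squares fit with at least 5 probes per segment and a penalty of 40 noise variances per breakpoint. Single probes far from their 5-probe window were first limited to 2.5 noise SDs from its median, and the mean of a segment was taken from the unlimited values. A segment mean above 0.2 was called a gain and one below -0.2 a loss. A mean above 0.8 was called a high-level gain and one below -0.8 a deep loss, and these were called focal when shorter than 10 Mb. Probes in segments called in at least 2 of the 4 normals were masked, which removed 8 probes on chromosome 4. On simulated arrays with the median noise of these data, every planted segment was found. At the highest noise, that of Trp53 tumour 8, 37.9% of planted segments of 30 probes at 0.5 were found, 82.1% of those of 10 probes at 1 and 91.8% of those of 200 probes at -0.3.

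The files name no genes, and the gene table at hand is on another build (GRCm38.p6) and shares no probe names with them, so no gene could be placed at a probe. Tests planned per gene were therefore run on 2254 bins of 1 Mb with at least 2 probes. The gene lists fixed beforehand and the antigen receptor loci could not be placed and have no result. In place of the engineered genes, the probes that follow the genotype labels were used. On chromosome 6 these were the probes above 1 in all 18 tumours labelled with the Met transgene. On chromosome 11 it was the probe below -0.5 in all 18 tumours with the conditional Trp53 allele and above it in all 8 others. The bins and both probe choices were made after the data were examined. The groups, the tests, the thresholds and most alternatives were fixed before the data were examined.

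Group means were compared by exact two-sided permutation tests over all arrangements of the samples, and shares of tumours by two-sided Fisher's exact tests. Comparisons by pathology permuted pathology within genotype with 100000 resamples. Chromosome means were tested for 19 autosomes in 3 pairs of genotypes, with Benjamini-Hochberg adjustment over the 57 tests. Bins were tested with limma (linear model and empirical Bayes) on the probe mean per bin, with all 26 tumours in the fit for comparisons of tumours, genotype as a covariate for pathology, and each tumour group with the 4 normals otherwise. A bin passed at an adjusted p under 0.05. The bins named are, per comparison, the 10 with the largest difference among those past the threshold, at least 5 Mb apart. High-level gains and deep losses shared by at least 2 tumours are also named. The exact test was tried on simulated data of 8 against 8 samples. Limma was tried on simulated data of the sizes compared, with bins drawn independently of each other.

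The headers place the arrays in 3 scan runs on 5 days and 2 scanners. Run 1 held the 8 Met tumours, run 2 the 10 MetTrp53 tumours with normals 1 and 2, and run 3, on the second scanner, the 8 Trp53 tumours with normals 3 and 4. Genotype and scan run therefore cannot be told apart between tumour groups, and Met tumours shared no run with any normal. The alternatives tried were signals corrected by limma's normexp with an offset of 50 (on median signals, since the files hold no mean signals), the authors' value table, probes well above background on every array, centring on the mode, subtraction of the normals' mean per probe, the scanner as a model term, averaged tumours of the same animal, and each sample left out in turn. Further alternatives were other thresholds (0.15 and 0.3), penalties (20 and 80), segments of at least 10 probes, no mask, bins with at least 1 or 3 probes, segment means per bin, robust variances with array weights, other sets of samples in the fit, and Fisher's exact test on calls per bin. A count of breakpoints with a step of at least 0.2 and comparisons within a scan run were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0 were used.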

Results

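DNA copy number was measured in mammary tumours of 3 genotypes and in normal mammary tissue, each against normal spleen DNA. The 8 Met tumours came from mice with MMTV-Met, a transgene that drives the Met receptor tyrosine kinase in the mammary gland. The 8 Trp53 tumours came from mice with 1 conditional allele of the tumour suppressor Trp53 (Trp53fl/+) and Cre recombinase. The 10 MetTrp53 tumours combined both. The 4 normals were 1 wild-type sample and 3 labelled with both engineered alleles. The 26 tumours came from 24 animals, since Trp53 tumours 4 and 5 shared an animal, as did 7 and 8. By pathology, 11 tumours were spindloid (1 of 8 Met, 7 of 10 MetTrp53 and 3 of 8 Trp53) and 15 were not. The label solid nodular carcinoma was given only to Met tumours, 4 of 8, so pathology varied with genotype. The median noise SD per array was 0.16 on the log2 scale. Genotype coincided with scan run, so a difference between tumour genotypes cannot be told apart from one between runs. Normals of the same run can show whether a change is absent there, but the run of the Met tumours held no normals.

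A single probe on chromosome 11, A_53_P121121 at 69399814 to 69399873 (NCBI36/mm8), was lost in every tumour with the conditional Trp53 allele and in no Met tumour. The mean log2 ratio was -1.30 ± 0.58 (SD, n = 10) in MetTrp53 tumours and -1.46 ± 0.42 (SD, n = 8) in Trp53 tumours, against 0.08 ± 0.11 (SD, n = 8) in Met tumours and -0.02 ± 0.11 (SD, n = 4) in normals. The loss was deepest in MetTrp53 tumour 4, at -2.64, and shallowest in MetTrp53 tumour 10, at -0.75. The difference from Met tumours was -1.39 in MetTrp53 (exact permutation p = 2.3e-05, two-sided) and -1.54 in Trp53 tumours (exact permutation p = 0.00016), the smallest p these group sizes can give. The probe was chosen for this contrast, so these p-values are not independent of the choice. MetTrp53 and Trp53 tumours differed by 0.15 (exact permutation p = 0.552), less than their spread. With normexp signals that difference was 0.73 (exact permutation p = 2.3e-05). Against the normals the differences were -1.29 in MetTrp53 (exact permutation p = 0.000999) and -1.44 in Trp53 tumours (exact permutation p = 0.00202), and in the authors' segmented table the latter was -0.17 (exact permutation p = 0.182). The normals of the same scan runs, at -0.10 to 0.14, lacked the loss. Against these 2 normals per run the differences were -1.33 in MetTrp53 (exact permutation p = 0.0303) and -1.39 in Trp53 tumours (exact permutation p = 0.0222).

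On chromosome 6, a pair of neighbouring probes was strongly raised in every tumour labelled with the transgene. The pair, A_53_P148041 (17442331 to 17442390) and A_53_P116890 (17476371 to 17476430), had a mean log2 ratio of 4.79 ± 1.29 (SD, n = 8) in Met tumours and 4.73 ± 0.78 (SD, n = 10) in MetTrp53 tumours. In Trp53 tumours it was 2.60 ± 2.13 (SD, n = 8), with 5 tumours between 3.67 and 4.69 and tumours 4, 5 and 8 at 0.05, 0.42 and -0.28. Among the normals, the pair was at 0.18 in the wild-type sample. In the 3 samples labelled with both alleles it was at 3.46, -0.06 and -0.28. Against the normals the pair was higher by 3.97 in Met (exact permutation p = 0.00202), 3.90 in MetTrp53 (exact permutation p = 0.002) and 1.78 in Trp53 tumours (exact permutation p = 0.109). The pair was chosen as raised in every Met and MetTrp53 tumour, so p-values for these tumours at the pair are not independent of the choice. Met and MetTrp53 tumours differed by -0.06 (exact permutation p = 0.895). Trp53 tumours were lower than Met tumours by a difference of -2.19 (exact permutation p = 0.0339), and this call was lost with normexp signals, with the scanner as a term, with animals averaged, and without any of Met tumours 1, 2 and 4 or Trp53 tumours 4, 5 and 8 (p up to 0.069 for the left-out tumours). The authors' value table omits these probes.

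The genome around this pair was amplified in all 10 MetTrp53 tumours, in 5 of 8 Trp53 tumours and in 2 of 8 Met tumours. In the other 6 Met tumours the pair stood alone, with its neighbours near the level of normal DNA. The adjacent probes, A_53_P121226 (17304428 to 17304487) and A_53_P137958 (17523589 to 17523648), had a mean log2 ratio of 4.33 ± 0.76 (SD, n = 10) in MetTrp53 tumours, 2.45 ± 2.02 (SD, n = 8) in Trp53 tumours and 1.49 ± 2.65 (SD, n = 8) in Met tumours. In the normals they were at 0.08 ± 0.15 (SD, n = 4). The 17 tumours with a high-level gain here shared the stretch from 17442331 to 17523648, of 3 probes, within a region from 13573260 to 18829387. In the gene order of the other build, Met on chromosome 6 is flanked by Cav1, Cav2 and Tes and by Capza2, St7 and Wnt2, but none of these could be placed on the probes.

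The amplification beside the pair was more frequent in MetTrp53 than in Met tumours (difference of 75 percentage points, Fisher's exact test, two-sided, p = 0.00151), and the adjacent probes were higher by 2.84 (exact permutation p = 0.00708). Trp53 and Met tumours differed by 37.5 percentage points (Fisher's exact test p = 0.315) and by 0.97 in the adjacent probes (exact permutation p = 0.441), which did not exceed the spread. MetTrp53 exceeded Trp53 tumours by 1.88 in the adjacent probes (exact permutation p = 0.0145), while the frequencies, which differed by 37.5 percentage points, missed the threshold (Fisher's exact test p = 0.0686). With the scanner as a model term the former was 1.69 (permutation p = 0.377), and with probes well above background on every array the frequency difference was 50 points (Fisher's exact test p = 0.0229). With tumours of the same animal averaged it was 16.7 points (Fisher's exact test p = 0.375). Against the normals the adjacent probes were higher by 4.25 in MetTrp53 tumours (exact permutation p = 0.000999), 2.37 in Trp53 tumours (exact permutation p = 0.0545) and 1.41 in Met tumours (exact permutation p = 0.319). The Trp53 excess over the normals passed with tumours of the same animal averaged, at 2.80 (exact permutation p = 0.0143), and also in the authors' value table and with normexp signals. Against the 2 normals of their own scan run, MetTrp53 tumours remained past the threshold and Trp53 tumours did not.

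**Figure D1:**
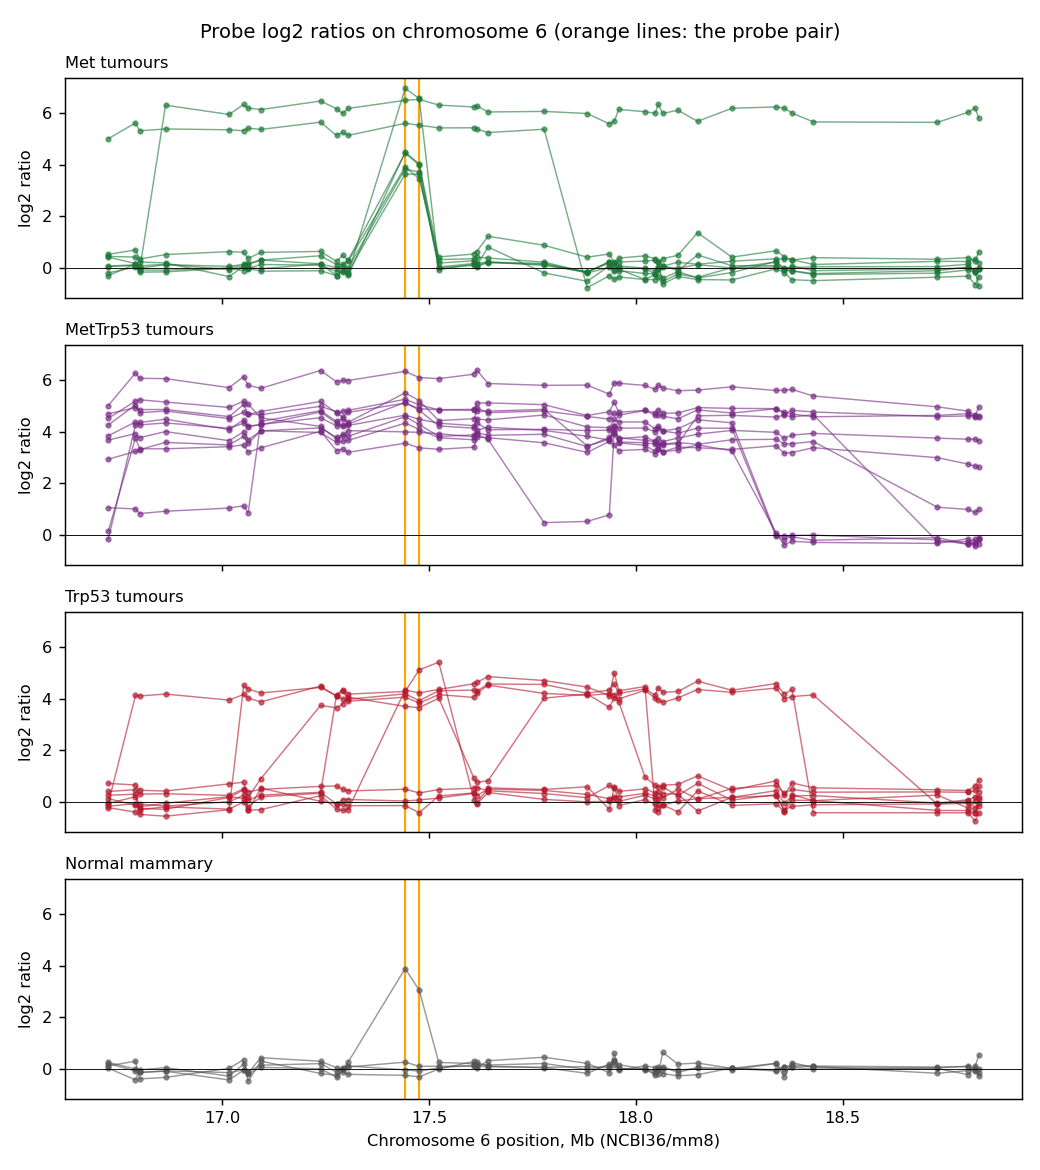
Log2 ratio of sample over spleen DNA (vertical axes) at each probe against position on chromosome 6 in Mb (horizontal axis), with 1 line per array, 1 panel per group and orange lines at the probe pair. In 6 of 8 Met tumours and in normal 2 the pair alone is raised, whereas the surrounding probes are raised as well in 10 of 10 MetTrp53, 5 of 8 Trp53 and 2 of 8 Met tumours.

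Large parts of the genome were gained or lost in tumours of every genotype. The share of autosomal probes in a gain or loss was 27.1% ± 12.8 (SD, n = 8) in Met, 29.3% ± 15.02 (SD, n = 10) in MetTrp53 and 37.7% ± 20.7 (SD, n = 8) in Trp53 tumours, and 0% in each of the 4 normals. The highest share, 75.8%, was in Trp53 tumour 5 and the lowest, 12.7%, in MetTrp53 tumour 2. The tumour groups did not differ by more than their spread (exact permutation p = 0.745 for MetTrp53 against Met, 0.242 for Trp53 against Met and 0.339 for MetTrp53 against Trp53). Each exceeded the normals (exact permutation p = 0.00202 for Met, 0.003 for MetTrp53 and 0.00808 for Trp53). Within scan run 3 alone, Trp53 tumours against 2 normals gave p = 0.0667 by the same exact test, and gains and losses called at 0.3 gave p = 0.0509 for MetTrp53 tumours. Trp53 exceeded Met tumours by 10.5 percentage points, by 17.0 with normexp signals (exact permutation p = 0.0188), by 0.11 with calls at 0.3 (exact permutation p = 0.987), by 6.49 with animals averaged and by 5.08 without Trp53 tumour 5.

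By a count chosen after the data were examined, tumours with the conditional Trp53 allele had more breakpoints within chromosomes than Met tumours. Counting breakpoints at which the segment mean stepped by at least 0.2, Met tumours had 5.88 ± 5.03 (SD, n = 8), MetTrp53 tumours 21.7 ± 6.09 (SD, n = 10) and Trp53 tumours 20.5 ± 6.76 (SD, n = 8). The normals had 3.75 ± 2.36 (SD, n = 4). The excess over Met tumours was 15.8 in MetTrp53 (exact permutation p = 0.000274) and 14.6 in Trp53 tumours (exact permutation p = 0.000622), and with each tumour left out in turn p stayed at or below 0.00124. Met tumour 2 had 18 such breakpoints and the other Met tumours 3 to 6. Against the 2 normals of the same scan run, the excess was 16.2 in MetTrp53 (exact permutation p = 0.0152) and 18.5 in Trp53 tumours (exact permutation p = 0.0222), the smallest p these sizes can give. This count of breakpoints with a step was not run with normexp signals, other penalties or averaged animals. The run of the Met tumours held no normals, so a low count in that run cannot be told apart from their genotype.

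The count fixed beforehand, of all segments whatever their step, was 34.8 ± 11.6 (SD, n = 8) in Met, 73.3 ± 17.7 (SD, n = 10) in MetTrp53, 45.4 ± 9.02 (SD, n = 8) in Trp53 tumours and 37 ± 18.7 (SD, n = 4) in normals. MetTrp53 exceeded Met tumours by 38.6 (exact permutation p = 0.00016) and Trp53 tumours by 27.9 (exact permutation p = 0.000914). Trp53 exceeded Met tumours by 10.6 (exact permutation p = 0.0657), and without Met tumour 2 or Trp53 tumour 1 by 13.2 and 12.1 (exact permutation p = 0.0199 and 0.0435). Normals 1 and 2, scanned with the MetTrp53 tumours, had 59 and 46 segments, and normals 3 and 4 had 22 and 21. The excess of MetTrp53 over Trp53 tumours was 1.2 with steps of at least 0.2 (exact permutation p = 0.712), 3.28 after subtraction of the normals' mean (exact permutation p = 0.502) and 0.05 with normexp signals (exact permutation p = 1). With normexp signals the excess over Met tumours was 3.18 (exact permutation p = 0.627).

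**Figure D2:**
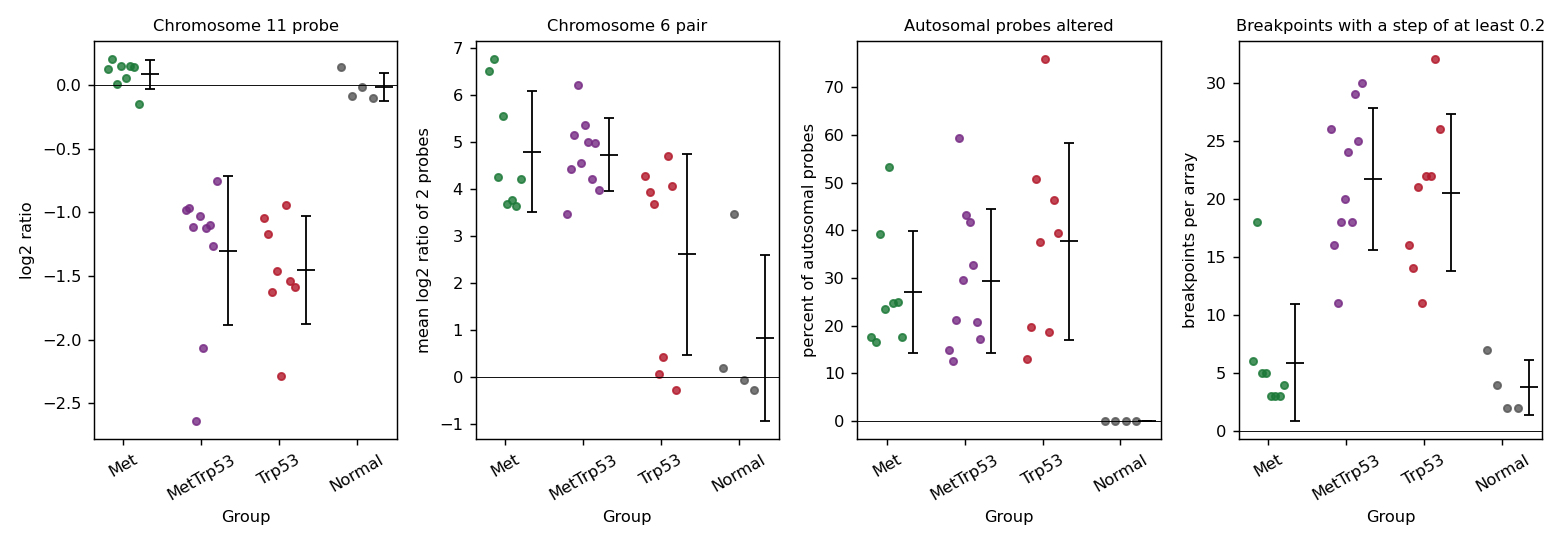
Values per array for 4 measures, the chromosome 11 probe (log2 ratio), the chromosome 6 pair (mean log2 ratio of 2 probes), the share of autosomal probes altered (percent) and the number of breakpoints with a step of at least 0.2, by group on the horizontal axis. Each point is 1 array and the black bars give the mean and SD; at the chromosome 11 probe every MetTrp53 and Trp53 tumour lies at or below -0.75.

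Counted by the chromosome mean, chromosome 15 was gained in 5 of 8 Met, 8 of 10 MetTrp53 and 7 of 8 Trp53 tumours. The chromosome means were 0.24 ± 0.21 (SD, n = 8), 0.28 ± 0.10 (SD, n = 10) and 0.28 ± 0.13 (SD, n = 8). A gain by the mean does not show that the whole chromosome was gained. The most often gained bins of chromosome 15, from 74000001, were gained in 21 of the 26 tumours. The end of chromosome 11, from 119000001, was gained in 7 MetTrp53 and 7 Trp53 tumours and in 0 Met tumours. The part of chromosome 11 from 19000001 was lost in 4 MetTrp53 and 4 Trp53 tumours and in 0 Met tumours. Chromosome 12 from 31000001 was lost in 5, 5 and 0 of these groups. Chromosomes 7 and 10 were each lost in up to 13 tumours, of which 1 was a Met tumour in either case. By the chromosome mean, gains of chromosome 1 occurred in 4 Met, 2 MetTrp53 and 0 Trp53 tumours and of chromosome 2 in 4, 1 and 1. In a single bin of chromosome 4, from 112000001 to 113000000, loss was called in 5 Met, 1 MetTrp53 and 4 Trp53 tumours. This bin lies beside the masked segment from 111634766 to 111955475, whose probes were too dim to measure copy number. The normals had no call at any of these positions.

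**Figure D3:**
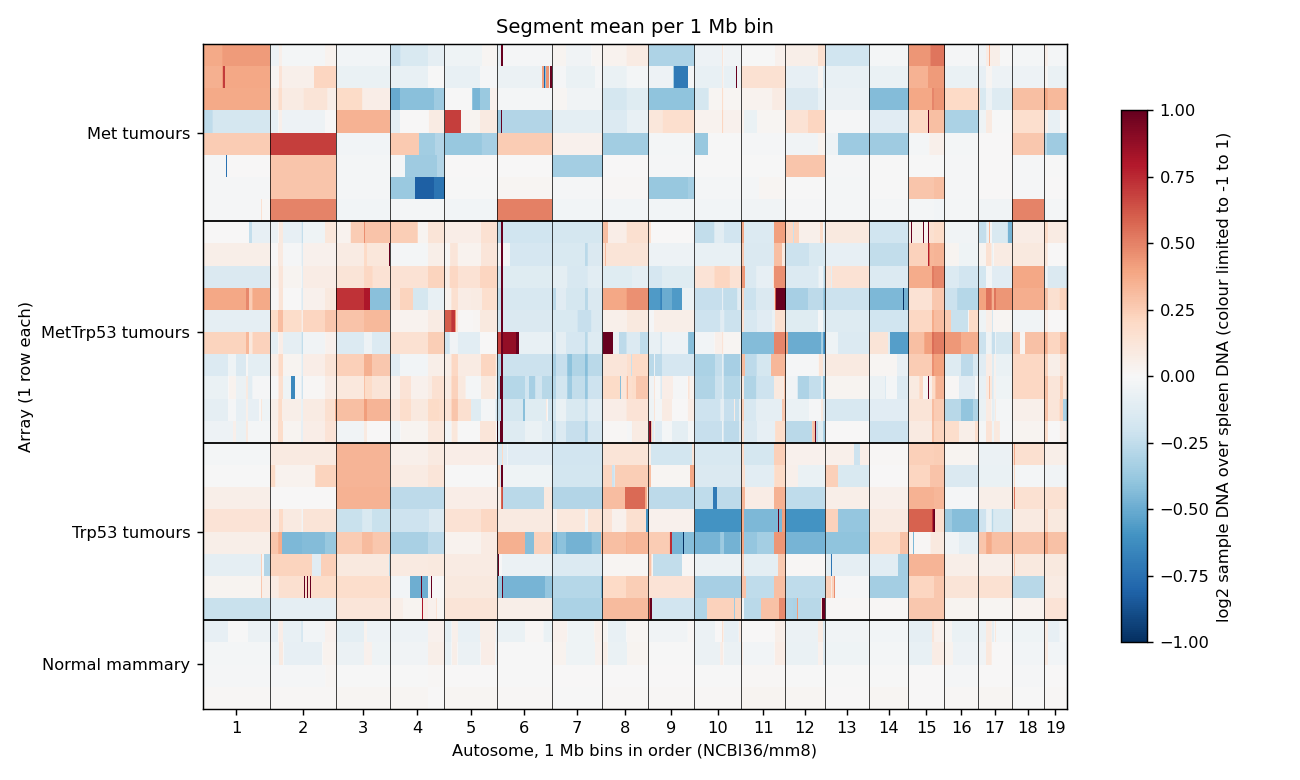
Segment mean (log2 ratio of sample over spleen DNA, colour, limited to -1 to 1) in 1 Mb bins along the 19 autosomes (horizontal axis) for the 30 arrays (vertical axis, 1 line of cells per array, by group). Chromosome 15 is gained in most tumours of every genotype, and the end of chromosome 11 in 7 MetTrp53 and 7 Trp53 tumours.

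Comparison of MetTrp53 with Met tumours asks what accompanies the conditional Trp53 allele on top of the transgene. Chromosome 4 was higher in MetTrp53 tumours, at 0.09 ± 0.08 (SD, n = 10) against -0.20 ± 0.23 (SD, n = 8; adjusted exact permutation p = 0.00886), and so was chromosome 8, at 0.15 ± 0.14 (SD, n = 10) against -0.07 ± 0.13 (SD, n = 8; adjusted exact permutation p = 0.0317). By limma, 183 bins differed, 83 higher and 100 lower in MetTrp53 tumours. The higher bins included 54 on chromosome 4, 10 on chromosome 11 between 102000001 and 121000000, and 4 on chromosome 6 from 15000001 to 19000000. Lower bins included 20 on chromosome 6 beyond 77000001, 18 on each of chromosomes 2 and 11, 16 on chromosome 7 and 13 on chromosome 12. The largest difference was at 16000001 to 17000000 on chromosome 6 (2.87 ± 0.59, SE, adjusted p = 0.0116, higher in 9 of 10 tumours). Next were chromosome 14 at 95000001 (-0.63 ± 0.11, SE), chromosome 6 at 148000001 (-0.50 ± 0.13, SE) and chromosome 12 at 48000001 (-0.49 ± 0.11, SE), each lower in 10 of 10 tumours. The other 6 named bins, on chromosomes 1, 4, 10, 11, 12 and 14, differed by -0.47 to 0.44. The chromosome 10 bin among them, at 71000001, is the one whose raised value in Met tumours is not supported as a gain against normals (below).

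The count of bins varied with centring, with the model and with single tumours. It rose with averaged animals, with all 30 samples in the fit and with the scanner as a term. The median difference of the 183 bins stayed at 0.31 in each of these fits, while the median SE fell from 0.088 to 0.083 or 0.084. Met and MetTrp53 tumours were scanned on the same scanner and each came from its own animal. The rise therefore says nothing about an effect of the scanner or of shared animals. Robust variances with array weights gave 780. Other alternatives lowered the count. It was 2 with each array centred on its mode. The median difference then went from 0.33 to 0.35 in the 83 higher bins and from -0.30 to -0.28 in the 100 lower ones, and the median SE of all 183 from 0.088 to 0.10. With only the SEs of that fit the count was 2, and with only its differences 188. With normexp signals 61 bins passed, 50 higher and 11 lower. The count was 0 with the authors' value table, where the median difference was 0.20 and the SE 0.084, and 0 with Fisher's exact test on calls. It was 29 without Met tumour 7, 440 without Met tumour 4, and 82 to 119 without any of Met tumours 3, 5, 6 and 8 or MetTrp53 tumours 1, 2, 7, 8 and 10. The chromosome 4 call held in each of the 6 alternatives tried for chromosomes and with every sample left out, while the chromosome 8 call was lost without any of Met tumours 2, 3 and 5 or MetTrp53 tumours 2, 4, 6, 7 and 8 (adjusted p up to 0.0977).

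Trp53 and Met tumours differed in genotype at both engineered loci. Chromosome 8 was higher in Trp53 tumours, at 0.22 ± 0.14 (SD, n = 8) against -0.07 ± 0.13 (SD, n = 8, adjusted exact permutation p = 0.00886). By the chromosome mean it was gained in 5 Trp53 and 0 Met tumours. By limma 231 bins differed, 92 higher and 139 lower in Trp53 tumours. Of the higher bins, 62 lay on chromosome 8 and 16 on chromosome 5. Of the lower bins, 35 lay on chromosome 12, 32 on chromosome 10, 23 on chromosome 7, 21 on chromosome 11 and 18 on chromosome 2. The largest differences were on chromosome 2 at 97000001 (-0.52 ± 0.10, SE, adjusted p = 0.0093, lower in 8 of 8 tumours) and chromosome 11 at 40000001 (-0.51 ± 0.11, SE, adjusted p = 0.0107, lower in 7 of 8). The other 8 named bins, on chromosomes 1, 3, 8, 10, 12 and 14, differed by -0.46 to 0.44. Among them is the bin at 71000001 on chromosome 10, with the same limit on its Met value. With the scanner as a model term 0 bins passed in limma, with 75 under an unadjusted p of 0.05. The median difference of the 231 bins was then 0.27 instead of 0.30, and the median SE rose from 0.083 to 0.18. With centring on the mode 73 passed, 5 higher and 68 lower. The median difference went from 0.30 to 0.25 in the 92 higher bins and from -0.29 to -0.34 in the 139 lower ones, and the median SE of all 231 from 0.083 to 0.095. The authors' value table gave 551 bins (77 higher and 474 lower), normexp signals 457 (131 and 326) and averaged animals 102. Without Trp53 tumour 5, Met tumour 5, Trp53 tumour 3 or Trp53 tumour 7 the count was 107, 131, 133 or 147, and the chromosome 8 call was lost in the authors' value table (adjusted exact permutation p = 0.0561).

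Comparison of MetTrp53 with Trp53 tumours asks what the transgene adds to the conditional Trp53 allele. Of the 2254 bins, 1 passed in limma, at 16000001 to 17000000 on chromosome 6, beside the probe pair. It was higher by 3.43 ± 0.59 (SE, adjusted p = 0.00412), at 3.85 ± 1.40 (SD, n = 10) against 0.42 ± 1.12 (SD, n = 8), and higher than the Trp53 mean in 10 of 10 MetTrp53 tumours. The pair itself was higher by 2.13 (exact permutation p = 0.00436), a p-value not independent of the choice of the pair as raised in every MetTrp53 tumour. No chromosome mean passed the adjusted threshold. These groups were scanned in different runs, and with the scanner as a model term 0 bins passed in limma, with 3 under an unadjusted p of 0.05. The bin then differed by 3.46 ± 1.34 (SE). Averaging tumours of the same animal also left 0 bins, with 184 under that p and this bin at 3.29 ± 0.68 (SE, adjusted p = 0.0854), and the pair differed by 0.13 with the scanner term (permutation p = 0.933).

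Focal high-level gains numbered 1.38 ± 1.30 (SD, n = 8) per Met, 4 ± 3.16 (SD, n = 10) per MetTrp53 and 4.38 ± 3.42 (SD, n = 8) per Trp53 tumour, and 0 in each normal. Apart from chromosome 6 near the pair, a stretch of chromosome 15 from 61783521 to 62063441 was amplified in Met tumour 4 and MetTrp53 tumours 1 and 8. A stretch of chromosome 9 from 6928903 to 8225804 was amplified in MetTrp53 tumour 10 and Trp53 tumour 8. Shared by pairs of tumours were chromosome 1 from 175677083 to 175792199 and chromosome 4 from 94474376 to 94589566 in Trp53 tumours 6 and 7, and 7 and 8. Others were chromosome 17 from 30212210 to 30650272 in Met tumour 1 and MetTrp53 tumour 1, and chromosome 18 from 9877107 to 10010073 in Trp53 tumours 1 and 3. Chromosome 6 from 147026625 to 147062388 was called in Met tumour 2, at 3.55, and in Trp53 tumour 5, at 0.84, just past the threshold of 0.8. Trp53 tumours 1, 3 and 4 were at 0.63, 0.64 and 0.74 there, and the other Trp53 tumours at -0.18 to 0.44. A deep loss on chromosome 13 from 22625074 to 22900355 was shared by MetTrp53 tumour 3, at -1.21, and Trp53 tumour 6, at -3.82. A segment of chromosome 15 near 77216592 was called in 9 tumours, gained in 6 and lost in 3. Its probes were dim, with a green signal 0.069 times the array median.

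The number of focal gains was higher by 2.63 in MetTrp53 (exact permutation p = 0.0355) and by 3 in Trp53 (exact permutation p = 0.0382) than in Met tumours, and MetTrp53 and Trp53 tumours differed by -0.38 (exact permutation p = 0.831). Both calls were lost under several alternatives, with normexp signals at p = 0.0606 and 0.0754 among them, and without any of Met tumours 3, 5, 6, 7 and 8. The MetTrp53 call was also lost without MetTrp53 tumour 1, 6, 8 or 10, and the Trp53 call without Trp53 tumour 3, 7 or 8. An amplification broken into several segments counted more than once. All 4 focal gains of MetTrp53 tumour 4 lay near the chromosome 6 pair, as did several of the 11 of tumour 10. The only focal gain of each of Met tumours 3, 7 and 8 was the dim segment near 77216592 on chromosome 15. The excess without these regions was not tested.

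Spindloid and other tumours were compared with genotype held fixed. The share of the genome altered was lower by 13.9 percentage points in spindloid tumours (difference of -13.9, permutation p = 0.071, two-sided), which missed the threshold. By limma 0 bins differed, with 535 under an unadjusted p of 0.05, while Fisher's exact test on calls gave 0 and robust variances with array weights 1. The share passed the threshold with the authors' value table (-18.1 points, permutation p = 0.00496), with calls at 0.3 (-14.7 points, permutation p = 0.00645), with centring on the mode (-14.9 points, permutation p = 0.0186) and narrowly with normexp signals (-12.9 points, permutation p = 0.0499). It also passed without MetTrp53 tumour 3 or Trp53 tumour 1 or 7 (permutation p = 0.0377, 0.0229 and 0.0376). The share rests on fixed thresholds, which DNA from normal cells in a tumour makes harder to reach. Tumour content was not measured, so such DNA cannot be told apart from a less altered genome.

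Against the 4 normals, the bins that differed in MetTrp53 tumours numbered 250, of which 72 were higher and 178 lower by limma. They included 63 higher bins on chromosome 15 and 3 on chromosome 6 around the pair, the largest at 17000001 to 18000000 (4.15 ± 0.34, SE, adjusted p = 5.9e-06, higher in 10 of 10 tumours). Lower bins were most numerous on chromosome 7, with 107, on chromosome 6 beyond 65000001, with 37, and on chromosome 11, with 24. In Met tumours 1 bin passed, on chromosome 10 at 71000001 to 72000000 (0.41 ± 0.07, SE, adjusted p = 0.0472, higher in 8 of 8 tumours), and it passed no more with centring on the mode (0.42, adjusted p = 0.0519) or with most single samples left out. Its difference fell to 0.13 with dim probes left out, 0.12 with normexp signals, 0.0056 in the authors' value table and -0.0020 with segment means, so it is not supported as a gain. In Trp53 tumours 0 passed, with 475 under an unadjusted p of 0.05. With tumours of the same animal averaged 278 passed, and with robust variances and array weights 677. The MetTrp53 count was 1 within scan run 2, 1 without normal 3, 119, 126 and 103 without normal 1, 2 or 4, 404 without MetTrp53 tumour 6, 29 with centring on the mode (27 higher and 2 lower) and 0 with the scanner as a term. With centring on the mode the median difference went from 0.27 to 0.29 in the 72 higher bins and from -0.20 to -0.17 in the 178 lower ones, and the median SE of all 250 from 0.053 to 0.066. With the scanner as a term that SE was 0.11. The Trp53 count was 364 without Trp53 tumour 4, the array with the fewest spots well above background, and 68 without Trp53 tumour 5.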

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

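The tests of explanations in this part were chosen only after the results were seen, except the test of dim probes on chromosome 4. Of 26 groups of values tested for a sample far from the others, 3 had such a sample, where chance gives about 1 in 20. Differences of the pathology effect between MetTrp53 and Trp53 tumours were tested for 3 measures, and none passed (exact permutation p = 0.333 for the chromosome 11 probe, 0.92 for the share altered and 0.525 for segments).

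At the chromosome 6 pair, normal 2 lay far above the other normals, at 3.46 against 0.18 for the nearest. All of normals 2, 3 and 4 carry the MMTV-Met;Trp53fl/+ label, and normals 3 and 4 lacked the raised pair. Scan run 3 was able to show a raised pair, since 5 of its arrays did, and a pair as high as in normal 2 would lie 13.7 times above the larger noise SD of normals 3 and 4, so the tables argue against both a blind scan run and noise. What stays open is a wrong genotype label for normals 3 and 4, a candidate explanation that the higher of their pair values, -0.063, is consistent with. No biological explanation was tested.

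MetTrp53 tumours had more segments than Trp53 tumours. Low steps between segments that differ between scan runs may account for this, since with steps of at least 0.2 the difference had an exact permutation p of 0.712, and the normals of the same runs differed in the same direction. Noise cannot be told apart as a cause. The mean noise SD was lower in MetTrp53 than in Trp53 tumours, by a difference of -0.031 (exact permutation p = 0.0572), which did not pass. Genotype as a cause stays open, untested, because each genotype had its own run.

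The depth of the chromosome 11 loss differed widely between tumours. Admixed DNA without the loss, for example from normal cells, may explain part of it. Over 16 animals the log2 ratio of the probe fell with the SD of segment means under 0.8 in size, a measure of how strongly the rest of the genome departs from normal (Pearson r = -0.92, permutation p = 1e-05, the smallest it can be, adjusted p = 3e-05; Spearman rho = -0.89, permutation p = 2e-05; r = -0.90 without the 2 farthest animals). Within scan run 2 r was -0.95 over 10 MetTrp53 animals (permutation p = 0.0005, adjusted 0.00075; -0.66 without the 2 farthest), and within run 3 it was -0.98 over 6 Trp53 animals (exact permutation p = 0.00139). Loss of the second allele in some tumours, with a more altered genome, predicts the same relation and had no test of its own. The files give no tumour content. The probe was at -2.64 and -2.07 in MetTrp53 tumours 4 and 6 and at -2.28 in Trp53 tumour 5. In a genome with 2 copies, loss of a single copy cannot give values this low, whatever the admixture. These values argue against that loss alone in these tumours, but the number of genome copies was not measured.

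The noise SD was 0.22 in MetTrp53 tumour 1 (nearest other 0.17) and 0.31 in Trp53 tumour 8 (nearest other 0.20), each far above its group. Chromosome X was in no comparison, and its median log2 ratio departed from 0 by more than 0.2 in 7 tumours, where the normals stayed within 0.08. It was -0.21 in Met tumour 2, -0.29, -0.22 and -0.72 in MetTrp53 tumours 1, 3 and 4, and -0.39, 0.23 and 0.22 in Trp53 tumours 1, 3 and 7. The segment on chromosome 4 from 111634766 to 111955475 that was called lost in normals had a median green signal of 0.032 times the array median, with 1.25% of its values well above background, so its probes were too dim to measure copy number.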

How the results depend on the processing

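The tests on other splits of the samples, the count of breakpoints with a step and the comparisons within scan runs were chosen only after the results were seen. Over 45 results, 427 alternatives were computed. Of these, 329 kept their direction and their side of the threshold (or a count within 1.5 times), 26 no longer passed, 17 newly passed, 13 turned direction and 42 moved a count by more. Every alternative, including each sample left out, kept the call of the loss at the chromosome 11 probe in MetTrp53 and Trp53 against Met tumours (differences of -1.59 to -0.18 with all samples) and the more frequent amplification beside the chromosome 6 pair in MetTrp53 than in Met tumours (62.5 to 75 points with all samples, p at most 0.00654). The chromosome 11 probe was chosen as separating these groups completely, so leaving out a sample could not have lost its call. Except where the construction of an alternative or a test is named, the cause was not tested.

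At the chromosome 11 probe, normexp signals gave 0.73 for MetTrp53 minus Trp53 (exact permutation p = 2.3e-05) and 0.24 for Met minus normals (exact permutation p = 0.0283), both newly past the threshold; the authors' table, whose values are averaged over segments, gave -0.17 for Trp53 minus normals. Met minus normals also passed without Met tumour 8, at 0.13 (exact permutation p = 0.0394). At the chromosome 6 pair, MetTrp53 minus Met was 0.016 with normexp and -0.23 to 0.21 with each sample left out, positive without Met tumour 1, 2 or 4 or MetTrp53 tumour 1 or 10. Trp53 minus Met no longer passed with normexp (-1.96), the scanner as a term (-0.20) or averaged animals (-1.68), and was -2.49 to -1.78 with samples left out. With the scanner as a term MetTrp53 minus Trp53 was 0.13 and no longer passed, and Trp53 minus normals was 2.77 and passed; this term rests on 2 normals per scanner, of which 1 carries the raised pair. At the adjacent probes the scanner term gave 1.69 for MetTrp53 minus Trp53, no longer passing. Trp53 minus normals passed with the authors' table (2.27), normexp (2.58), averaged animals (2.80) and without Trp53 tumour 4, 5, 6 or 8, in a range of 2.04 to 2.72. With dim probes left out, the amplification was 50 points more frequent in MetTrp53 than in Trp53 tumours and passed, while averaged animals gave 16.7 points (p = 0.375).

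The share altered in MetTrp53 minus Met tumours was 2.21 points and turned to -0.44 in the authors' table, -7.03 with calls at 0.3 and -2.87 after subtraction of the normals' mean, none past the threshold; it ranged from -1.13 (without MetTrp53 tumour 4) to 5.93 with samples left out. Trp53 minus Met was 10.5, and 17.0 with normexp, where it passed; it was 0.11 with calls at 0.3 (p = 0.987), 6.49 with averaged animals and 5.08 without Trp53 tumour 5. Against normals, MetTrp53 gave 11.8 with calls at 0.3, and Trp53 gave 37.7 within scan run 3, where fewer samples leave a smallest possible p of 0.0222; neither passed. For spindloid minus other tumours the share passed with the authors' table (-18.1), calls at 0.3 (-14.7), centring on the mode (-14.9) and normexp (-12.9). It ranged from -17.2 to -10.3 with samples left out, passing without MetTrp53 tumour 3 or Trp53 tumour 1 or 7.

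The number of segments in MetTrp53 minus Met tumours was 3.18 with normexp and no longer passed. Trp53 minus Met passed with a step of at least 0.2 (14.6) or a penalty of 80 (10.9) and ranged from 8.39 to 13.2 with samples left out, passing without Met tumour 2 or Trp53 tumour 1. MetTrp53 minus Trp53 no longer passed with the step (1.2), the normals' mean subtracted (3.28) or normexp (0.05). Met minus normals was -2.25 and turned to 4.88 in the authors' table, 2.13 with the step and 8.63 with normexp, and ranged from -7.58 to 5.08 with samples left out, positive without normal 1 or 2; it never passed. MetTrp53 minus normals no longer passed with normexp (11.8) or within scan run 2 (20.8). Trp53 minus normals passed with the step (16.8), a penalty of 80 (9.5) and within scan run 3 (23.9), and a penalty of 20 turned it to -3.63.

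Focal high-level gains in MetTrp53 minus Met tumours no longer passed with thresholds of 0.15 and 0.6 (2.65), normexp (3.35), or penalties of 20 (2.95) and 80 (2.43), and ranged from 1.85 to 3 with samples left out. Trp53 minus Met no longer passed in the authors' table (3.13), with thresholds of 0.3 and 1 (2.63), the normals' mean subtracted (2.75), normexp (3.13), penalties of 20 (3.13) and 80 (2.25), dim probes left out (2.5) or at least 10 probes per segment (2.63), and ranged from 2.20 to 3.48. MetTrp53 minus Trp53, at -0.38, turned to 1.15 in the authors' table, 0.05 with the normals' mean subtracted, 0.23 with normexp, 0.18 with a penalty of 80 and 0.083 with animals averaged. It ranged from -1.15 to 0.43 with samples left out, positive without Trp53 tumour 7 or 8, and never passed. Of the chromosome tests, 2 to 5 passed with samples left out.

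Counts of bins moved most. Centring on the mode shifted 2 of 30 arrays by over 0.1, MetTrp53 tumour 4 by -0.16 and Trp53 tumour 5 by 0.26. It gave 2 bins (1 higher, 1 lower) for MetTrp53 against Met, 73 (5 and 68) for Trp53 against Met, 0 for Met and 29 (27 and 2) for MetTrp53 against normals. All 183 bins of MetTrp53 against Met kept their direction with this centring, with differences larger in the 83 higher bins and smaller in the 100 lower ones. With only its SEs the count was 2, and with only its differences 188 (115 and 73), so the larger SEs account for most lost calls there. Normexp gave 61 (50 and 11), 457 (131 and 326), 12 for MetTrp53 against Trp53, and against normals 0 for Met, 217 (92 and 125) for MetTrp53 and 41 for Trp53. The authors' table gave 0 (660 under an unadjusted p of 0.05 in limma) and 551 (77 and 474) against Met, and 0 for Met and 36 for MetTrp53 against normals. The scanner as a term gave 291 and 0 against Met, 0 for MetTrp53 against Trp53, and 0 for Met and MetTrp53 against normals, with 167 and 128 unadjusted; this term raised the median SE of the bins called in Trp53 against Met from 0.083 to 0.18. Robust variances with array weights gave 780, 524, 44, 1 for spindloid tumours, and 463, 1045 and 677 against normals. Segment means gave 53 and 87 against Met and 0 for Met against normals; all 30 samples in the fit gave 310 and 353 against Met; Fisher's exact test on calls gave 0 in the 3 pairs of genotypes. Averaged animals gave 339 and 102 against Met, 0 for MetTrp53 against Trp53 and 278 for Trp53 against normals. MetTrp53 against Trp53 had 6 bins with at least 1 probe per bin, 5 with only both groups in the fit and 3 with dim probes left out, which gave 0 for Met against normals. Within scan run 2, MetTrp53 against normals had 1.

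With samples left out, MetTrp53 against Met ranged from 29 to 440, Trp53 against Met from 107 to 340, MetTrp53 against Trp53 from 1 to 3, Met against normals from 0 to 3, MetTrp53 against normals from 1 to 404 and Trp53 against normals from 0 to 364. Bins past the threshold in Met against normals were 0 without any of Met tumours 3 to 8 or normals 1, 2 and 4.

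Among 100 splits of the same samples, the real one included, 1 gave as many bins as the real 183 for MetTrp53 against Met (highest other 159). For Trp53 against Met, 1 gave as many as the real 231 (highest other 103). These counts argue against chance. They do not exclude it, since only 100 of 43758 and of 6435 possible splits were drawn. Since some Trp53 tumours share an animal, splits of animals were run as well. With animals averaged, 2 of 100 splits, the real one included, gave as many as the real 102 for Trp53 against Met. The other gave 168, more than the real count, so the evidence against chance is weaker there. For MetTrp53 against normals, only the real one of 100 splits reached 250 bins (highest other 10). With animals averaged, only the real one reached 278 for Trp53 against normals (highest other 82). The normals varied less than the tumours, with an SD of chromosome 15 means of 0.006 against 0.098 in MetTrp53 and 0.13 in Trp53 tumours. A split that puts tumours among the normals can lose calls through this spread alone. These counts against normals therefore cannot tell chance apart from unequal spread. The splits of animals were also run only for comparisons that gave bins after averaging. For the single bins of MetTrp53 against Trp53 and Met against normals, 4 and 2 of 100 splits gave at least 1 bin, and among them were splits with 69 and 314. These shares are under 5 in 100, but a single bin is weak evidence against chance when other splits give so many. For spindloid tumours and for Trp53 tumours as single samples against normals the real count was 0, which all 100 splits reach by definition (highest others 67 and 135), so the splits cannot tell. Bins of the same segment are not independent of each other, and why some splits gave many times the real count was not tested. Evidence against chance leaves scan runs open, since the genotypes were scanned in different runs.

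Subtraction of the normals' mean gives no value against normals, the authors' table none for the pair, and a fit of only both groups none for pathology. Signal over background limits dim probes, such as those on chromosome 4 and near 77216592 on chromosome 15.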

Other observations

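The tests on pathology and on gene identity in this part, and the counts over all choices of tumours and of animals, were chosen only after the results were seen. Several tumours carried amplifications of their own. In Met tumour 2, chromosome 6 from 145973320 to 146908421 was at 5.28 and chromosome 10 from 116687125 to 117527065 at 4.04, while the region beside the chromosome 6 pair was not amplified. In MetTrp53 tumour 6, chromosome 8 from 10516230 to 12454054 was at 4.72. In Trp53 tumour 4, which lacked the chromosome 6 amplification, chromosome 11 from 102897358 to 103636038 was at 2.98. In Trp53 tumour 8, which also lacked it, chromosome 9 from 7273870 to 10251674 was at 3.79, and chromosome 9 from 6168919 to 8225804 was at 2.05 in MetTrp53 tumour 10. Trp53 tumour 7 had 6 separate high-level gains on chromosome 2 between 91631697 and 112339653, at 1.71 to 1.89.

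Trp53 tumours 7 and 8 shared an animal, and the chromosome 6 pair was at 4.05 in tumour 7 and at -0.28 in tumour 8. Trp53 tumours 4 and 5 shared another animal and both lacked the amplification. MetTrp53 tumour 6 came from the animal of normal 2, and the adjacent probes on chromosome 6 were at 4.39 in the tumour and at 0.25 in the normal sample.

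The chromosome 11 loss was shallower in spindloid tumours, at -1.09 ± 0.21 (SD, n = 10) against -1.73 ± 0.56 (SD, n = 8) in other tumours with the conditional allele. The difference within genotype was 0.66 (exact permutation p = 0.0058, two-sided). It was 0.91 among MetTrp53 and 0.38 among Trp53 tumours. The test treated tumours of the same animal as independent and was not run with animals averaged, so its p-value may be too small. Trp53 tumours 7 and 8 shared an animal and were nearly equal, at -1.54 (spindloid) and -1.58 (not spindloid). Spindloid tumours may hold more DNA without the loss, a hypothesis found and tested on the same arrays, and losing only 1 allele more often would give the same difference.

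The probe pair and the chromosome 11 probe may lie in the engineered genes. Both probes of the pair (2 of 2) lie on chromosome 6, which carries Met, and the single chromosome 11 probe (1 of 1) on chromosome 11, which carries Trp53. Chromosomes 6 and 11 hold 5.66% and 7.05% of all mapped probes, so this does not decide it, and the builds differ. Of all 735471 choices of as many of the 24 animals, 2 gave a probe as sharply split as that on chromosome 11 (highest other 1). A probe can match at most 1 choice, and the rule was set after this probe was seen. A small share was therefore given in advance, and it does not exclude chance. For the pair, 7315 of 134596 choices of animals (5.43%) gave as many probes in all their tumours (highest other 2), as did 2.15% of all choices of single tumours and 6 of 100 drawn first. These counts cannot test the link with the transgene label, since 5 Trp53 tumours raise the same probes through the amplification. Where the neighbours are not raised, the pair was at 3.63 to 6.75 in 6 Met tumours and at 0.05, 0.42 and -0.28 in Trp53 tumours 4, 5 and 8, but the pair was chosen as raised in every Met tumour. If the pair does lie in Met, the raised pair without raised neighbours in 6 Met tumours and normal 2 would be the transgene, and the amplification in Trp53 tumours that of the gene's own locus; neither was tested beyond these values.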
